A study of Arabidopsis thaliana with 48 samples.

How the data were processed

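The deposited data are reads per gene of RNA from shoot apices enriched for the apical meristem, from 4 genotypes at 3, 4, 5 and 6 weeks of short days. Each library came from 15 pooled apices, with 3 per genotype and week and TruSeq library preparation, per the labels' protocols. The deposited counts are whole numbers per gene in 48 columns, per the file headers, and 3358 genes had no read in any column. TopHat2, SAMtools, HTSeq and DESeq2 and the TAIR10 genome build are listed with no versions or settings, per the submitters' processing notes. Counts of sequenced and mapped reads for the WT and quintuple libraries were deposited as a table. The authors also deposited tables of differential genes, whose log2 fold changes between 2 genotypes at a week were used as given. The mean signal in these tables (a mean of normalized counts) is given per gene, per the file headers, and was compared with the mean over the 24 columns of the 2 genotypes. The p-value columns in the tables deposited by the authors hold p and adjusted p. The quintuple tables list genes with an absolute fold change over 2 and adjusted p under 0.01, per the deposited description sheet, and the largest adjusted p in the chr4-2 and qem2 tables is under 0.05.

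Gene names were taken from a RefSeq table (assembly TAIR10.1, GCF_000001735.4), which matched 26719 identifiers (98.2%), and the order of genes on it was used for neighbours. In the shallowest library (2.91 M reads) 10 reads are 3.33 CPM. The common dispersion gave a biological coefficient of variation of 14.7%, and TMM factors ran from 0.874 to 1.05. Reads were amplified by PCR and no molecular identifiers are stated, so that counting intervals and floors cover counting error alone. The strand setting of the counting is not stated, so that reads of antisense, overlapping or paralogous genes cannot be excluded from a gene's count.

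The column labelled qem2 5 weeks replicate 3 equals that of quintuple 5 weeks replicate 3 at every gene and was left out. This departs from the planned use of 48 columns, was decided after the data were seen, and leaves 2 libraries for qem2 at 5 weeks, whose spread is pooled with the other groups.

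Tests were run with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 in R 4.3.3. The 47 libraries in 16 groups entered 1 quasi-likelihood fit (estimateDisp, glmQLFit with robust, glmQLFTest) after TMM normalization and filterByExpr, which left 19566 genes. Genes were called at Benjamini-Hochberg adjusted p under 0.05 with no fold minimum. The comparisons were chr4-2 against WT, qem2 against quintuple and quintuple against WT at each week, 6 against 3 weeks in each genotype, and 4 tests of differences between effects. CPM are on TMM-scaled library sizes. Of the 224 genes in 19 lists fixed before the data were examined, 193 were tested. Each list was tested with camera at a preset correlation of 0.01 and adjusted over 304 tests, and its members also with BH over the list alone. Lists for leaf mesophyll, vascular tissue, reproductive organs and seeds stand for other tissues that an apex sample could hold, and those for wounding, heat, cold and the clock for handling and time of sampling.

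Named genes are the mutated loci, the 5 largest rises and 5 largest falls per genotype comparison and for WT over time, up to 4 called members per list and comparison, and the 5 genes of smallest adjusted p per difference test. The largest rises and falls were taken among called genes with groups that did not overlap and a mean of at least 1 CPM in the higher group. Fewer are named where genes repeat across weeks and for the time course of the mutants. A fold against a group with no read is a bound, set at 3 reads over the group, and genes with 1 to 3 reads in the lower group are given as levels or as a ratio with a 95% counting interval.

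Replicate numbers were checked as pairs by correlating the residuals of libraries with equal numbers. All 3 pairs passed 0.1 in 5 of 12 genotype comparisons (chr4-2 at 4 and 5 weeks, qem2 at 3 and 4 weeks, quintuple at 5 weeks). So did both pairs of qem2 at 5 weeks (0.101 and 0.167), under the minimum of 3 pairs set for the check. No label states a pairing, so replicates entered unpaired. A block raised counts in all 12 comparisons.

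Alternatives were RLE factors, no count filter, DESeq2 Wald tests, a fit of the compared libraries alone, a replicate block, an absolute log2 fold change of at least 1, each library left out, camera with an estimated correlation, and all 48 columns, the last chosen after seeing the data. The procedure was tested only on counts simulated for chr4-2 against WT at 6 weeks (19566 genes, 200 of at least 1 CPM changed). It recovered 55.2% at 1.5-fold, 82.1% at 2-fold and 98.5% at 4-fold, and 4.85% of calls were false there.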

Results

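RNA of shoot apices enriched for the apical meristem of Arabidopsis thaliana was sequenced from plants grown in short days for 3, 4, 5 or 6 weeks. The 4 genotypes were the wild type (WT, Col), chr4-2, quintuple and qem2. The chr4-2 line carries an insertion in CHR4, also called PKR1, which encodes a chromatin remodeller of the CHD family. The quintuple line lacks SVP, FLC, FT, TSF and SOC1, a set of regulators of flowering time, and qem2 is a mutant recovered in that background. Each of the 16 groups of a genotype and a week had 3 libraries of 15 pooled apices, which makes 48 columns of read counts. The column labelled qem2 5 weeks replicate 3 held the counts of quintuple 5 weeks replicate 3 at every gene, so it was left out and qem2 at 5 weeks had n = 2. Assigned reads per library ran from 2.91 M (qem2 6 weeks replicate 1) to 19.75 M, with a median of 14.2 M. Levels are CPM (reads scaled to library size) as mean ± SD over the libraries of a group, n = 3 unless stated. Log2 fold changes and adjusted p come from edgeR fits over 47 libraries with Benjamini-Hochberg (BH) adjustment over 19566 tested genes, and a gene was called when its adjusted p was under 0.05. A library is written as its genotype and replicate number, so that WT 1 is replicate 1 of WT in the weeks compared.

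Levels of the mutated loci were examined before any other gene. CHR4 (AT5G44800) fell in chr4-2 at every week, from 171 ± 10.0 CPM in WT to 76.0 ± 9.36 in chr4-2 at 3 weeks and from 230 ± 10.8 to 103 ± 1.29 at 6 weeks. Its adjusted p were 5.63e-13, 9.18e-13, 2.99e-12 and 6.61e-13 in week order. In qem2 CHR4 was not lower: it rose over quintuple at 3 weeks, from 178 ± 10.1 to 251 ± 13.7 CPM (log2 0.50, adjusted p = 0.000168), and at 4 weeks (log2 0.37, adjusted p = 0.00642). It was not called at 5 weeks (adjusted p = 0.328) or 6 weeks (adjusted p = 0.255). SVP (AT2G22540) fell in quintuple against WT at every week, with 52.6 ± 4.39 CPM against 136 ± 14.8 at 6 weeks (log2 -1.37, adjusted p = 1.36e-08). SOC1 (AT2G45660) had more reads in quintuple than in WT at 3, 4 and 5 weeks (log2 1.65, 1.26 and 0.97, adjusted p = 0.00102, 0.00129 and 0.0111), and at 6 weeks it was not called (adjusted p = 0.143). FLC (AT5G10140), a repressor of flowering, was not called in quintuple at any week. It fell in chr4-2 at 6 weeks, to 0.247 ± 0.142 CPM from 3.48 ± 0.970 (log2 -3.75, adjusted p = 0.000291). It also fell in qem2 at 5 weeks, to 1.72 ± 0.795 (n = 2) from 7.60 ± 0.825, and at 6 weeks, to 1.02 ± 0.556 from 4.60 ± 1.22 (adjusted p = 0.0177 and 0.00822). FT and TSF had at most 6 reads in any group and were not tested. Reads of SVP, FLC and SOC1 remained in quintuple and qem2, and reads that lie outside a mutation do not check a genotype. The set of the 4 tested loci holds CHR4 itself, so that its lower rank in chr4-2 at each week restates the mutation (camera adjusted p = 0.01, 0.00493, 0.00398 and 0.000102, and 0.0491, 0.0268, 0.0225 and 0.00186 with estimated correlation). CHR4 was the only locus of the set to fall at 3, 4 and 5 weeks, joined by FLC at 6 weeks (1, 1, 2 and 2 loci adjusted over the list alone), and the medians at 3 and 4 weeks were above 0 (log2 0.20 and 0.15). The same set, in which CHR4 alone was called, ranked higher in qem2 than in quintuple at 3 weeks (camera adjusted p = 0.045, and adjusted p = 0.129 with estimated correlation). The FLC fall in qem2 at 5 weeks ended with all 48 columns and without quintuple 1 or 2 or qem2 1 or 2 (adjusted p from 0.0301 to 0.368 over the fits without 1 library) and that at 6 weeks without qem2 3 (0.0106 to 0.111). The CHR4 rise at 4 weeks ended without quintuple 3 or qem2 2 (0.00968 to 0.127). The SOC1 rise at 5 weeks ended without WT 2 or quintuple 3 (0.000369 to 0.122), and FLC became called in chr4-2 at 5 weeks without WT 3 (adjusted p = 0.0158). Fits of the compared libraries alone ended the CHR4 rise at 4 weeks and the SOC1 rise at 5 weeks, and SOC1 became called in chr4-2 at 6 weeks (adjusted p = 0.405, 0.235 and 0.0362). With replicate number as a block FLC was called lower in qem2 at 4 weeks (adjusted p = 0.0238).

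WT at 6 weeks was compared with WT at 3 weeks to describe the time course in short days. FD, a bZIP factor that binds FT, went from 8.66 ± 2.15 to 33.9 ± 1.27 CPM (log2 1.95, adjusted p = 3.96e-13), and AGL42, AGL19 and SPL3 rose by log2 2.23, 2.13 and 2.80. Of the genes that give floral meristems their identity, LFY rose from 0.942 ± 0.102 to 3.65 ± 0.783 CPM, UFO by log2 1.65, LMI1 by 0.41 and FUL by 1.23. The meristem genes STM and AIL5 rose (log2 1.35 and 1.09), while the boundary genes BOP1 and BOP2 fell (log2 -1.74 and -1.43). The vascular genes XCP1 (25.3 ± 3.51 to 5.81 ± 1.72 CPM), PP2-A1, XCP2 and VND6 fell (log2 -1.70, -1.66 and -1.82 for the last 3). The largest rises were those of AT5G44260, which encodes a zinc finger protein (15.4 ± 3.56 against 0.0619 ± 0.107 CPM), HFR1, a bHLH factor of light signalling (11.9 ± 2.20 against 0.0454 ± 0.0786 CPM), YUC9 (at least 18.6-fold), CYP705A13 (at least 13.8-fold) and THI2.1 (90.1 ± 118 against 0.960 ± 1.66 CPM). The largest falls ended at 0 reads at 6 weeks and were at least 85.3-fold for AT2G38390, 85.5-fold for AT1G26390, 64.6-fold for AT4G01390, 63.1-fold for AT4G38080 and 58.5-fold for AT5G37690. In all 7426 genes were called, 3678 higher and 3748 lower at 6 weeks.

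By list, 10 of 13 floral promoters rose in WT (10 adjusted over the list alone), and the list ranked higher (camera adjusted p = 3.16e-09, and 0.00101 with estimated correlation). Among 20 genes of shoot meristem and boundary 11 rose and 2 fell, as they did adjusted over the list alone (camera adjusted p = 0.01, adjusted p = 0.469 with estimated correlation). Of 5 genes of stamen, carpel and ovule development SPL8 (log2 1.97), CRC (2.91), JAG (0.66) and 1 more rose and SHP1 fell (-2.83), equally so adjusted over the list alone (camera adjusted p = 0.0121, adjusted p = 0.0525 with estimated correlation). Of 11 vascular genes 9 fell, 11 adjusted over the list alone (camera adjusted p = 0.00041, adjusted p = 0.448 with estimated correlation). No other list was called as a set. Floral meristem and organ identity had 4 rises among 9 genes (camera adjusted p = 0.175), and floral repressors had 6 rises and 3 falls among 14 (0.371), with TFL1 at log2 2.55, AP2 at 0.66, FLM at 0.54 and SNZ at -1.90. Gibberellin genes had 6 rises and 4 falls among 19 (0.415), GID1A, RGA, GAI and RGL1 rising by log2 0.81, 0.70, 0.81 and 0.88. Of 15 Polycomb, trithorax and CHD factors 5 rose (0.189), among them SYD, LHP1, ATX2 and BRM (log2 0.58, 0.33, 0.34 and 0.41), and of 4 genes of embryo and seed maturation OLEO1 rose (log2 2.70; list 0.643). Of 10 photosynthesis genes CA1, RBCS2B, RCA and RBCS1A fell (log2 -4.30, -1.84, -1.05 and -0.67; list 0.101). For these 6 lists the counts adjusted over the list alone were the same. Salicylic acid defence had 2 rises (NPR1 0.75, WRKY70 1.55) and 2 falls (PR1 -2.03, PAD3 -3.08) among 9 genes, 4 and 2 adjusted over the list alone (list 0.561). Auxin had 3 rises (TAA1, IAA29 2.88, YUC1 0.65) and 2 falls (IAA19 -2.10) among 8, 4 and 2 adjusted over the list alone (0.189). The cell cycle list had 1 rise (CYCD3;1 0.35) and 3 falls (AUR1 -0.51, AUR2 and CDKB2;2 -0.33) among 10 (0.558), the flavonoid and anthocyanin list 1 fall (PAP1 -1.52) among 9 (0.519) and the mutated loci 3 rises and 1 fall among 4 (0.104), each count unchanged adjusted over the list alone. No member of wounding, touch and jasmonate (13 tested, 0.769), heat shock (3, 0.875), cold and abscisic acid response (7, 0.922) or circadian clock (10, 0.74) changed, and none did adjusted over the list alone. The median of the cold list was below 0 (log2 -0.02) while its test pointed up. In fits without 1 library the call ended for LMI1 without WT 3 weeks 1 (adjusted p from 0.00381 to 0.0618), FUL without WT 3 weeks 1 or 3 or WT 6 weeks 1 or 2 (0.0283 to 0.141), LHP1 (0.00599 to 0.051) and PR1 (0.00415 to 0.0616) without WT 6 weeks 1, and PAD3 without WT 3 weeks 1 (0.00294 to 0.819). It also ended for AUR2 without WT 3 weeks 3 (0.00592 to 0.0708), CDKB2;2 without WT 3 weeks 2 or 3 or any WT 6 weeks library (0.0285 to 0.234) and YUC1 without WT 3 weeks 3 or WT 6 weeks 1 or 2 (0.0176 to 0.0957).

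Flowering genes also rose from 3 to 6 weeks within each mutant. FUL, a MADS-box gene of floral identity, rose from 0.579 ± 0.120 to 23.3 ± 7.72 CPM in quintuple (log2 5.34), by log2 3.98 in qem2 and in chr4-2 from 0.664 ± 0.266 to 7.55 ± 0.962 CPM. LFY rose by log2 3.02 in quintuple, 2.16 in chr4-2 and 0.67 in qem2, and SPL4 by 5.30, 3.48 and 4.16 in the same order. FLC fell in chr4-2 and qem2 (log2 -6.01 and -2.88) and was not called in quintuple (adjusted p = 0.195). The jasmonate gene LOX2 rose by log2 4.63 in quintuple and 3.76 in qem2. Calls numbered 8989 in chr4-2 (4476 higher, 4513 lower at 6 weeks), 8128 in quintuple (4016 and 4112) and 6949 in qem2 (3522 and 3427). Among 13 floral promoters 11 rose in chr4-2, 13 in quintuple and 12 in qem2 (11, 13 and 13 adjusted over the list alone), with camera adjusted p of 3.58e-11, 5.17e-25 and 3.98e-19 (0.000402, 2.11e-06 and 1.43e-05 with estimated correlation). Floral identity genes had 5, 8 and 3 rises among 9 (5, 9 and 2 adjusted over the list alone), with camera adjusted p of 0.0117 in chr4-2 (adjusted p = 0.159 with estimated correlation), 3.57e-05 in quintuple (0.0148) and 0.0728 in qem2. Vascular genes had 9, 9 and 10 falls among 11 (10, 9 and 10 adjusted over the list alone), with camera adjusted p of 0.00277, 1.11e-05 and 2.31e-07 that were lost with estimated correlation (adjusted p = 0.521, 0.307 and 0.202). Photosynthesis genes had 7, 8 and 4 falls among 10 (8, 8 and 4 adjusted over the list alone). That list was called in chr4-2 and quintuple (camera adjusted p = 0.00372 and 0.00535, adjusted p = 0.624 and 0.634 with estimated correlation). The shoot meristem and boundary list was called in the same 2 lines (camera adjusted p = 0.00424 and 0.00087, adjusted p = 0.413 and 0.307 with estimated correlation), with 11 and 12 rises and 2 falls each among 20 genes (11 and 12 rises, 2 and 3 falls adjusted over the list alone). The list of stamen, carpel and ovule development was called in quintuple alone, with 3 rises and 1 fall among 5, as adjusted over the list alone (camera adjusted p = 0.0121, adjusted p = 0.0525 with estimated correlation). The LFY rise in qem2 ended without any of the 6 libraries compared (adjusted p from 0.0528 to 0.189).

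**Figure D1:**
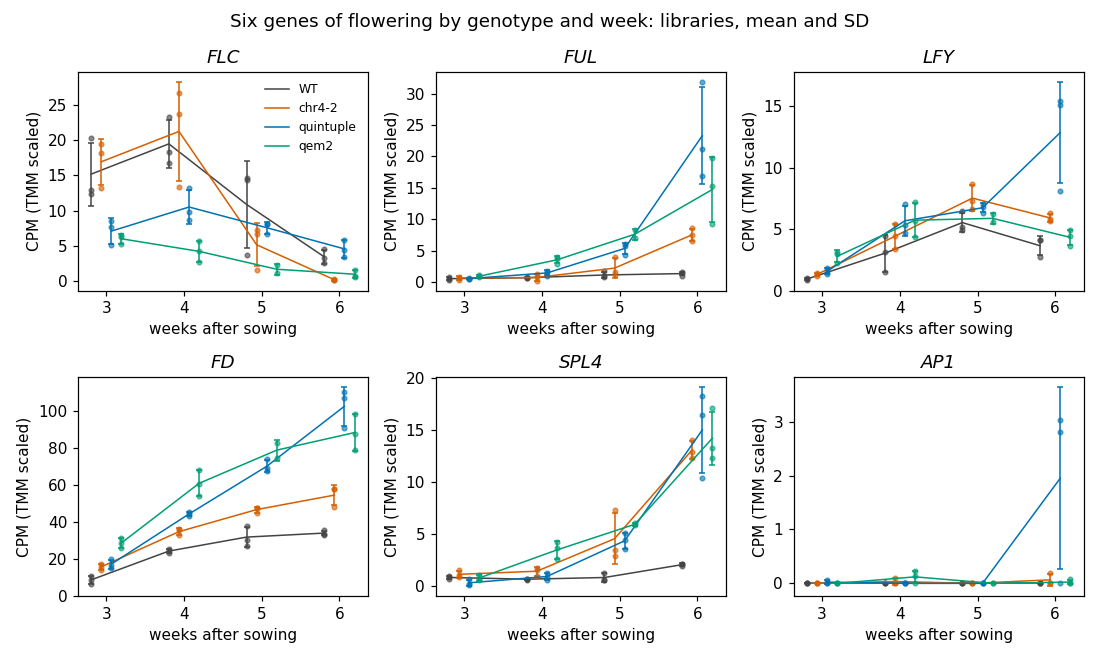
CPM of FLC, FUL, LFY, FD, SPL4 and AP1 in short-day apices by week and genotype. Points are libraries and lines join group means, with bars of 1 SD. At 6 weeks FUL had 23.3 ± 7.72 CPM in quintuple and 1.37 ± 0.296 in WT.

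The comparison of chr4-2 with WT asks how loss of the remodeller alters transcripts of the apex in otherwise wild-type plants. At 3 weeks MRD1 (AT1G53480) had 37.8 ± 3.44 CPM in chr4-2 and 0.0315 ± 0.0545 in WT, 1646 reads against 1, a ratio of 1370 (95% exact counting interval 245 to 54000). AT2G04050 was at least 26.1-fold higher, AT4G28811, which encodes a bHLH protein, at least 17.4-fold, and AT2G25330, which encodes a TRAF-like protein, at least 16.3-fold, all with 0 reads in WT. AT1G48180 had 2.08 ± 0.514 CPM against 0.0315 ± 0.0545. Of the genes that fell, AT4G25320, which encodes an AT-hook protein, had 14.2 ± 0.752 CPM against 61.7 ± 1.79 (log2 -2.13, adjusted p = 2.88e-14) and AT5G61820 fell by log2 2.57. JRG21 (0.0539 ± 0.0933 against 8.37 ± 14.1 CPM), Prx37 and DIN11 (log2 -2.83 and -2.68) fell with an SD in WT above the mean. Among floral promoters FD rose from 8.66 ± 2.15 to 15.7 ± 1.63 CPM (log2 0.84, adjusted p = 0.00022) and SPL15 by log2 0.65, which made 2 of 13 genes, also adjusted over the list alone (camera adjusted p = 0.0512). The boundary gene CUC1 (log2 0.97) was the only 1 of 20 meristem and boundary genes to rise, also adjusted over the list alone (camera adjusted p = 0.0525). Calls numbered 160, with 108 higher and 52 lower in chr4-2. Without WT 1 the count was 102. A fit of the 6 compared libraries alone ended the calls of Prx37, DIN11, AT5G61820, FD, SPL15 and CUC1. Calls ended in fits without 1 library for JRG21 (adjusted p from 0.00676 to 1), Prx37 (0.0108 to 0.977) and DIN11 (0.00123 to 0.919) without WT 1 or any chr4-2 library, SPL15 without WT 1 or 3 or chr4-2 2 or 3 (0.0454 to 0.18) and CUC1 without any of the 6 (0.0673 to 0.204).

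At 4 weeks MRD1 and AT1G48180 were again among the largest rises in chr4-2, MRD1 with 43.9 ± 1.11 CPM against 0.0798 ± 0.0705 in WT and AT1G48180 with 1.99 ± 0.443 against 0.0351 ± 0.0608. CMT1, a chromomethylase gene, rose to 3.66 ± 1.07 CPM from 0.146 ± 0.197 (log2 5.08, adjusted p = 5.58e-06) and AT2G29500, a gene of a small heat shock protein, to 8.44 ± 1.22 from 0.266 ± 0.106 (adjusted p = 1.62e-09). AT2G16210 was at least 17.1-fold higher. ZYP1b, which encodes a protein of the synaptonemal complex, fell to 1.59 ± 0.167 CPM from 9.84 ± 1.23 (log2 -2.61, adjusted p = 2.64e-08), and PORA, GRP3S, AT5G61820 and AT4G25320 fell (log2 -2.96, -2.47, -2.41 and -2.18). FD (log2 0.52) was the only 1 of 13 floral promoters to rise, also adjusted over the list alone, and the list ranked higher (camera adjusted p = 0.00994, adjusted p = 0.202 with estimated correlation). GA2, an enzyme gene of gibberellin synthesis, rose by log2 0.57, 1 of 19 gibberellin genes against 2 adjusted over the list alone (camera adjusted p = 0.595), a list whose median (log2 -0.05) and test differed in sign. The seed storage gene CRU3 was at least 7.66-fold higher, 1 of 4 genes of embryo and seed maturation, also adjusted over the list alone (camera adjusted p = 0.0654). The flavonoid and anthocyanin list ranked higher with 0 of 9 genes called, 1 adjusted over the list alone (camera adjusted p = 0.0059, adjusted p = 0.469 with estimated correlation). Calls numbered 214, 142 higher and 72 lower. Without WT 3 the count was 137. It was 60 in a fit of the 6 libraries alone, where PORA, FD and GA2 lost their calls. The fits without 1 library ended the calls of PORA without WT 1 or chr4-2 2 or 3 (adjusted p from 0.00511 to 0.209) and GRP3S without WT 1 or 2 or any chr4-2 library (0.0332 to 0.19). The call of FD ended without any WT library or chr4-2 2 or 3 (0.0273 to 0.102) and that of GA2 without WT 2 or 3 or chr4-2 1 or 3 (0.0169 to 0.322). The call of CRU3 ended without WT 1 or 3 or chr4-2 1 (0.0282 to 0.128).

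At 5 weeks genes of flowering, of the meristem and of seeds were among those that rose in chr4-2. SPL4 went to 4.58 ± 2.42 CPM from 0.844 ± 0.403 in WT (log2 2.39, adjusted p = 2.66e-05), and SPL15, FD and SPL9 rose by log2 0.70, 0.56 and 0.47. These were 4 of 13 floral promoters, also adjusted over the list alone (camera adjusted p = 0.000505, adjusted p = 0.0575 with estimated correlation). WUS, which maintains the stem cells of the meristem, had 0.916 ± 0.254 CPM against 0.141 ± 0.181, and CUC1 and STM rose by log2 0.95 and 0.61. They were 3 of 20 meristem and boundary genes, also adjusted over the list alone (camera adjusted p = 0.00087, adjusted p = 0.307 with estimated correlation). The seed genes CRU3 and ATS1 were at least 12.7-fold and 14.5-fold higher. The embryo and seed list had CRU3 as the only 1 of 4 genes called, 2 adjusted over the list alone (camera adjusted p = 0.0388, adjusted p = 0.12 with estimated correlation). MRD1 had 54.1 ± 3.53 CPM against 0.0335 ± 0.0581, AT1G48180 3.54 ± 0.367 against 0.0488 ± 0.0424, and SPIK, a potassium channel gene, 1.69 ± 0.360 against 0.0335 ± 0.0581. The largest falls were those of TDR1, an ERF factor (0.0475 ± 0.0426 against 1.02 ± 0.417 CPM), AT2G16380, JAL33, AT3G16660 and GRP3S (log2 -3.80, -3.67, -3.54 and -3.46). The gibberellin genes GA2OX1 and GA2 rose (log2 1.93 and 0.74), 2 of 19 against 4 adjusted over the list alone (camera adjusted p = 0.169). CESA7 was the only 1 of 11 vascular genes to rise (log2 0.81), also adjusted over the list alone (camera adjusted p = 0.686). PR5 was the only 1 of 9 genes of salicylic acid defence to fall (log2 -1.32), also adjusted over the list alone (0.215). Calls numbered 453, 285 higher and 168 lower. WT 3 lay apart from WT 1 and 2, with 32.7 on the first principal component (PC1) against 7.13 and 7.49 and 8.84 on PC2 against -41.4 and -25.7. The count was 282 without WT 2, 255 without chr4-2 2 and 291 without chr4-2 3, and 169 in a fit of the 6 libraries alone. That fit ended the calls of JAL33, SPL4, SPL15, FD, SPL9, GA2OX1, CUC1, STM and CESA7. Leaving out 1 library ended the calls of JAL33 without WT 2 or any chr4-2 library (adjusted p from 0.00387 to 0.283) and AT3G16660 without WT 3 or chr4-2 1 or 2 (0.0047 to 0.139). The call of FD ended without WT 1 (0.00111 to 0.0736) and that of SPL9 without WT 1 or 2 or chr4-2 2 or 3 (0.0195 to 0.142). The call of GA2OX1 ended without WT 2 (0.00201 to 0.0642) and that of CUC1 without WT 1 or chr4-2 2 (0.00889 to 0.109). The call of WUS ended without WT 1 or 2 or chr4-2 2 (0.00293 to 0.103) and that of STM without WT 3 or chr4-2 2 (0.0148 to 0.25). The call of CESA7 ended without WT 1 or 3 or any chr4-2 library (0.00244 to 0.36) and that of PR5 without WT 2 (0.00688 to 0.0602).

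At 6 weeks FUL had 7.55 ± 0.962 CPM in chr4-2 and 1.37 ± 0.296 in WT (log2 2.51, adjusted p = 1.07e-05), SPL4 13.1 ± 0.894 against 2.08 ± 0.111 (log2 2.66, adjusted p = 2.1e-07) and FD 54.4 ± 5.44 against 33.9 ± 1.27 (log2 0.68, adjusted p = 0.000245). UFO, FDP and SPL15 rose as well (log2 1.33, 1.43 and 0.64), and the floral repressors MAF4 and TOE2 fell (log2 -1.26 and -0.45) while TOE3 rose (log2 0.96). CYP79F1 and BCAT4, 2 genes of aliphatic glucosinolate synthesis, fell to 8.85 ± 4.18 CPM from 132 ± 115 and to 22.3 ± 10.1 from 195 ± 153 (adjusted p = 0.00126 and 0.00637), as did the methyltransferase gene HMT3 (log2 -2.96). MRD1 was at least 779-fold, SVL4 at least 39.9-fold and CRU3 at least 29.5-fold higher, with 0 reads in WT. AT2G24696, which encodes a B3 factor, had 7.34 ± 1.52 CPM against 0.0897 ± 0.0641, and BGLU11, a beta-glucosidase gene, 7.59 ± 2.40 against 0.105 ± 0.0913. Besides FLC, AT4G25320 (8.09 ± 1.39 against 65.3 ± 9.30 CPM) was among the largest falls. By list, 4 of 13 floral promoters rose (5 rises and 1 fall adjusted over the list alone; camera adjusted p = 6.36e-06, and 0.0148 with estimated correlation). Floral identity genes had 2 rises among 9 (4 adjusted over the list alone; camera adjusted p = 0.00149, adjusted p = 0.0575 with estimated correlation). Meristem and boundary genes had 3 rises among 20, CUC1, BOP2 and KNAT6 (log2 1.37, 0.71 and 0.82), against 7 adjusted over the list alone (camera adjusted p = 0.00506, adjusted p = 0.418 with estimated correlation). The embryo and seed list had 1 rise among 4, also adjusted over the list alone (camera adjusted p = 0.0205, adjusted p = 0.0749 with estimated correlation). Floral repressors had 1 rise and 2 falls among 14, also adjusted over the list alone (camera adjusted p = 0.812). Gibberellin genes had 1 rise, GA2, and 2 falls, GA2OX6 and GA3 (log2 0.60, -1.15 and -0.28), among 19, against 2 and 2 adjusted over the list alone (0.561). CESA7 rose (log2 1.19) alone among vascular genes (0.6) and PR5 fell (log2 -1.75) alone among genes of salicylic acid defence (0.873, with a median of log2 0.27 although the test pointed down), both also adjusted over the list alone. Calls numbered 784, 450 higher and 334 lower. The count was 484 without WT 3 and 451 without chr4-2 3. With the 6 libraries alone CYP79F1, BCAT4, HMT3, GA2OX6 and GA3 were not called. A library left out ended the calls of BCAT4 without WT 1 or chr4-2 3 (adjusted p from 0.00458 to 0.0861) and HMT3 without WT 1 or any chr4-2 library (0.0215 to 0.239). The call of SPL15 ended without WT 3 (0.00145 to 0.0724) and that of MAF4 without any WT library or chr4-2 2 or 3 (0.0372 to 0.12). The call of TOE2 ended without any of the 6 (0.0894 to 0.174) and that of GA2 without WT 3 or chr4-2 2 (0.0202 to 0.0907). The call of GA2OX6 ended without WT 1 or 2 or chr4-2 1 or 3 (0.0128 to 0.163) and that of GA3 without WT 1 or 3 or chr4-2 1 or 3 (0.0314 to 0.231). The call of KNAT6 ended without WT 2 or 3 or chr4-2 1 (0.0193 to 0.104).

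The comparison of qem2 with quintuple asks what the added mutation changes in plants that already lack 5 regulators of flowering time. At 3 weeks FD had 28.6 ± 2.50 CPM in qem2 and 17.2 ± 2.47 in quintuple (log2 0.73, adjusted p = 0.000447), and SPL15 rose by log2 0.68. Thus 2 of 13 floral promoters rose, also adjusted over the list alone (camera adjusted p = 0.00637, adjusted p = 0.176 with estimated correlation). The repressors MAF5 and MAF4 rose (log2 1.41 and 1.29), 2 of 14, also adjusted over the list alone (camera adjusted p = 0.045, adjusted p = 0.329 with estimated correlation). STM and CUC1 rose (log2 0.64 and 0.93), 2 of 20 meristem and boundary genes against 5 adjusted over the list alone (camera adjusted p = 0.000169, adjusted p = 0.231 with estimated correlation). The largest rises were those of AT2G25330 (1.24 ± 0.266 against 0.0351 ± 0.0608 CPM), CHX2, a cation exchanger gene (1.12 ± 0.316 against 0.0534 ± 0.0472), AT4G05380 (1.02 ± 0.0933 against 0.0896 ± 0.155), AT1G48180 (1.99 ± 0.239 against 0.147 ± 0.0607) and AT4G36600 (log2 3.45). ZYP1b fell to 1.36 ± 0.357 CPM from 7.56 ± 1.04 (adjusted p = 2.02e-07) and AT4G25320 to 15.3 ± 1.21 from 64.8 ± 4.51 (adjusted p = 3.52e-14), as did QQS, AT2G20870 and AT3G24360 (log2 -2.42, -2.20 and -2.10). Calls numbered 206, 147 higher and 59 lower in qem2. The count was 105 without quintuple 1, 128 without quintuple 3 and 130, 121 and 136 without qem2 1, 2 and 3. In a fit of the 6 libraries alone it was 1072, with 496 higher and more lower, and QQS was not called. Calls ended on leaving out 1 library for CHX2 without quintuple 1 (adjusted p from 0.0109 to 0.11) and AT4G05380 without quintuple 1 or 2 or qem2 2 (0.00364 to 0.182). The call of AT4G36600 ended without quintuple 1 or 3 or qem2 1 (0.0127 to 0.122) and that of AT2G20870 without quintuple 1 or 3 or qem2 1 or 2 (0.0231 to 0.306). The call of AT3G24360 ended without quintuple 1 or qem2 1 or 2 (0.0177 to 0.0995) and that of SPL15 without quintuple 1 or qem2 2 (0.00472 to 0.0999). The call of MAF5 ended without quintuple 1 or 3 or qem2 1 or 2 (0.0157 to 0.172), MAF4 (0.063 to 0.208) and CUC1 (0.0593 to 0.18) without any of the 6 and STM without any quintuple library or qem2 2 or 3 (0.0448 to 0.139).

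At 4 weeks AT2G29500 had 6.30 ± 0.474 CPM in qem2 and 0.212 ± 0.193 in quintuple (log2 4.72, adjusted p = 5.81e-09). AT4G29760 (1.04 ± 0.472 against 0.0214 ± 0.0371 CPM), AT4G28811 (1.48 ± 0.479 against 0.0360 ± 0.0623), AT1G48180 and AT1G61550 (log2 4.27 and 3.97) made up the rest of the largest rises. AT4G25320 fell to 8.06 ± 2.11 CPM from 51.4 ± 4.93 (log2 -2.67, adjusted p = 8.44e-17), and AT3G24360, AT3G28550, CYSD2 and UCC1 fell (log2 -3.71, -3.22, -2.86 and -2.45). SPL4 went to 3.50 ± 0.841 CPM from 0.942 ± 0.332 (adjusted p = 0.000984) and FD rose by log2 0.46, 2 of 13 floral promoters, also adjusted over the list alone (camera adjusted p = 0.0502). MAF5 was the only 1 of 14 floral repressors to rise (log2 1.47) against 2 adjusted over the list alone (camera adjusted p = 0.838), with a median below 0 (log2 -0.06) under a test that pointed up. GA3 alone fell (log2 -0.35) among 19 gibberellin genes, also adjusted over the list alone (camera adjusted p = 0.42). Calls numbered 240, 153 higher and 87 lower, and with replicate number as a block within the week the count was 367. In a fit of the 6 libraries alone it was 26, 18 of them higher. AT4G28811, AT1G48180, AT1G61550, AT3G24360, AT3G28550, CYSD2, UCC1, SPL4, FD, MAF5 and GA3 lost their calls there. The count was 148 without quintuple 2, 394 without qem2 1 and 152 without qem2 2. The calls of AT3G28550 ended without quintuple 2 or qem2 2 or 3 (adjusted p from 0.0266 to 0.0975), of UCC1 without quintuple 2 or 3 or qem2 3 (0.0204 to 0.167). The call of FD ended without any quintuple library or qem2 1 or 2 (0.0306 to 0.356), of MAF5 without quintuple 1 or 2 or qem2 1 (0.0125 to 0.106). The call of GA3 ended without quintuple 1 or 3 or qem2 2 or 3 (0.0329 to 0.0926).

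At 5 weeks, with 2 qem2 libraries, AT1G48180 had 3.93 ± 0.0790 CPM in qem2 (n = 2) and 0.0523 ± 0.0906 in quintuple, SVL4 1.5 ± 0.385 (n = 2) against 0.0339 ± 0.0588 and AT2G29500 5.85 ± 0.0664 (n = 2) against 0.233 ± 0.169. AT4G27850 and AT4G28811 rose by log2 5.04 and 4.45. AT4G25320 fell to 8.69 ± 1.86 CPM (n = 2) from 68.7 ± 2.71 (log2 -2.98, adjusted p = 5.17e-16), ZYP1b, AT2G30670 and AT2G43670 fell (log2 -2.32, -2.79 and -2.32), and AT3G24360 had 0.106 ± 0.0587 CPM (n = 2) against 1.27 ± 0.366. The repressor MAF5 rose (log2 1.81), 1 of 14, also adjusted over the list alone (camera adjusted p = 0.924), and CRU3 was at least 15.2-fold higher, 1 of 4 genes of embryo and seed maturation, also adjusted over the list alone (0.104). None of 13 floral promoters, 9 floral identity genes or 20 meristem and boundary genes changed, adjusted over all genes or over the list alone (camera adjusted p = 0.914, 0.989 and 0.215). Calls numbered 276, 195 higher and 81 lower. The count was 167 without quintuple 2, 107 without qem2 1 and 111 without qem2 2, 157 in a fit of the 5 libraries alone and 43 with all 48 columns. The fit of 5 ended the calls of AT3G24360, AT2G30670, AT2G43670 and MAF5. Calls did not outlast the loss of 1 library for AT3G24360 without qem2 1 or 2 (adjusted p from 0.00479 to 0.158), AT2G30670 (0.0412 to 0.392) and AT2G43670 (0.0108 to 0.492) without quintuple 1 or 2 or qem2 1 or 2, MAF5 without quintuple 2 or qem2 1 (0.0114 to 0.238) and CRU3 without qem2 2 (0.00122 to 0.091).

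At 6 weeks LFY had 4.33 ± 0.626 CPM in qem2 and 12.8 ± 4.13 in quintuple (log2 -1.52, adjusted p = 0.000149). AP1 had 0.0241 ± 0.0418 against 1.95 ± 1.69, 1 read against 86 (ratio 64.3, 95% exact counting interval 11.2 to 2570). Its groups overlapped, with 2.81, 0 and 3.04 CPM in the quintuple libraries and 0, 0 and 0.0723 in those of qem2. AGL72 had 0.226 ± 0.136 against 1.97 ± 0.458 (adjusted p = 0.00682). DESeq2 called neither AP1 nor AGL72. The boundary gene CUC2 had 4.2 ± 1.32 CPM against 9.65 ± 2.22 (log2 -1.13, adjusted p = 0.00105). Floral identity genes had 2 falls among 9 (4 adjusted over the list alone; camera adjusted p = 0.00398, adjusted p = 0.0927 with estimated correlation). Meristem and boundary genes had 1 fall among 20 (2 adjusted over the list alone; camera adjusted p = 0.00104, adjusted p = 0.307 with estimated correlation). AGL72 was the only 1 of 13 floral promoters to fall, also adjusted over the list alone (camera adjusted p = 0.095). Among repressors MAF4 fell and MAF5 rose (log2 -2.30 and 1.38), 1 each of 14, against 1 rise and 2 falls adjusted over the list alone (0.561). GA2OX1 rose (log2 1.36), 1 of 19 gibberellin genes, also adjusted over the list alone (0.792). NPR1 (log2 0.47) was 1 of 9 genes of salicylic acid defence, against 3 rises and 1 fall adjusted over the list alone (0.169). CRU3, at least 18.3-fold higher, was 1 of 4 seed genes, also adjusted over the list alone (0.302, with a median of log2 -0.19 although the test pointed up). The cold and abscisic acid list ranked higher with 0 of 7 genes called, 2 adjusted over the list alone (camera adjusted p = 0.0447, adjusted p = 0.485 with estimated correlation). The largest rises further held AT5G40000 (at least 26.0-fold), CHX2 (2.23 ± 1.31 against 0.0262 ± 0.0454 CPM), AT1G48180 (log2 5.01) and TRI (1.14 ± 0.471 against 0.0230 ± 0.0398). The largest falls further held HMT3 (log2 -4.78), AT4G25320 (6.09 ± 0.794 against 60.2 ± 0.826 CPM), AT3G24360 (log2 -3.20) and AT2G43670 (0.0723 ± 0.125 against 1.03 ± 0.696). Calls numbered 560, 359 higher and 201 lower. On PC4 qem2 1, 2 and 3 lay at -32.0, -6.45 and -34.2 (other weeks -14.8 to -6.0). The count was 357 and 310 without quintuple 1 or 2, and 1158 and 236 without qem2 2 or 3. It was 115 in a fit of the 6 libraries alone, where HMT3, MAF4, MAF5, GA2OX1, CUC2 and NPR1 lost their calls. Lost without 1 library were the calls of AT5G40000 without any quintuple library or qem2 1 or 3 (adjusted p from 0.0041 to 0.286) and HMT3 without quintuple 2 or qem2 3 (0.00317 to 0.183). The call of AT2G43670 ended without quintuple 3 or qem2 2 (0.0012 to 0.0698) and that of AGL72 without qem2 3 (0.0115 to 0.102). The call of AP1 ended without any qem2 library (0.00339 to 0.228, and not tested without quintuple 1 or 3) and that of MAF5 without quintuple 2 or qem2 3 (0.0313 to 0.109). The call of GA2OX1 ended without quintuple 1 or 2 or qem2 3 (0.0167 to 0.439) and that of NPR1 without quintuple 1 or 2 or qem2 1 or 3 (0.00394 to 0.254).

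The comparison of quintuple with WT asks how loss of SVP, FLC, FT, TSF and SOC1 together alters the apex in short days. At 3 weeks FD had 17.2 ± 2.47 CPM in quintuple and 8.66 ± 2.15 in WT (log2 0.98, adjusted p = 3.44e-05) and SPL9 46.8 ± 4.40 against 29.8 ± 4.00 (log2 0.65, adjusted p = 0.00467). The starch-related gene QQS had 22.0 ± 15.2 CPM against 0.269 ± 0.152 and BXL3, a beta-xylosidase gene, 18.6 ± 6.83 against 0.633 ± 0.0663. AT1G22460 was at least 13.6-fold and AT1G34440 at least 13.3-fold higher, and PAP16 had 1.1 ± 0.529 CPM against 0.0934 ± 0.0929. PXMT1 was at least 181-fold lower (0 reads against 12.2 ± 20.3 CPM in WT), and AT4G16260, AZI1 and EARLI1 fell (log2 -6.03, -4.31 and -3.98), as did GRP9 (0.0587 ± 0.0537 against 2.75 ± 2.49 CPM). FD and SPL9 were the 2 of 13 floral promoters that rose, against 7 rises and 1 fall adjusted over the list alone (camera adjusted p = 4.29e-08, and 0.00244 with estimated correlation). Sets with 0 genes called that ranked higher were stamen, carpel and ovule development (3 of 5 rose adjusted over the list alone; camera adjusted p = 3.63e-05, and 0.00101 with estimated correlation). So did gibberellin genes (4 of 19 adjusted over the list alone; 0.00398, and 0.0406). With 0 genes called, vascular genes (0 of 11 adjusted over the list alone; camera adjusted p = 0.0447, adjusted p = 0.747 with estimated correlation) and auxin genes (0 of 8; 0.02, adjusted p = 0.129 with estimated correlation) also ranked higher. Salicylic acid defence (2 of 9 fell adjusted over the list alone; camera adjusted p = 0.0165, adjusted p = 0.469 with estimated correlation) and the flavonoid and anthocyanin list (0 of 9 adjusted over the list alone; 0.00994, adjusted p = 0.488 with estimated correlation) ranked lower, again with 0 genes called. Calls numbered 79, 45 higher and 34 lower in quintuple. The count was 37 without WT 1, 52 without WT 3, 30 without quintuple 1 and 38 without quintuple 2. In a fit of the 6 libraries alone it was 184, 94 of them higher, while QQS, AT4G16260 and GRP9 lost their calls. Calls that 1 library decided were PAP16 without WT 3 (adjusted p from 0.00514 to 0.0708), PXMT1 (0.00211 to 0.697) and AT4G16260 (0.00251 to 0.997) without WT 1 or any quintuple library, GRP9 (0.0219 to 0.39) and EARLI1 (0.0102 to 0.28) without WT 1 or 3 or any quintuple library and SPL9 without WT 1 (0.00741 to 0.0988).

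At 4 weeks SPL9 had 76.3 ± 8.06 CPM in quintuple and 35.8 ± 0.708 in WT (log2 1.09, adjusted p = 2.29e-07), AGL19 19.4 ± 2.82 against 6.44 ± 1.68 and AGL42 24.1 ± 3.18 against 7.98 ± 1.21, and FDP rose by log2 1.80. With them 8 of 13 floral promoters rose, 10 adjusted over the list alone (camera adjusted p = 7.12e-16, and 5.18e-05 with estimated correlation). Floral identity genes had 2 rises, SEP4 and LFY (log2 1.36 and 0.84), and 1 fall, LMI1 (log2 -0.40), among 9, against 6 and 1 adjusted over the list alone (camera adjusted p = 0.037, adjusted p = 0.264 with estimated correlation). Of 19 genes of gibberellin metabolism and signalling 7 rose, among them GA2OX2 (24.7 ± 7.17 against 6.01 ± 1.24 CPM), GA2OX1, GA20OX2 and GAI (log2 2.20, 1.81 and 0.59), also adjusted over the list alone (camera adjusted p = 0.00845, adjusted p = 0.0603 with estimated correlation). SPL8 rose (log2 1.71), 1 of 5 genes of stamen, carpel and ovule development against 2 adjusted over the list alone (camera adjusted p = 0.0202, adjusted p = 0.0723 with estimated correlation). All 3 heat shock genes fell, HSP101, HSP70 and HSFA2 (log2 -0.62, -2.24 and -2.22), also adjusted over the list alone (camera adjusted p = 0.0165, adjusted p = 0.308 with estimated correlation). FLS1 and CHI also fell (log2 -0.95 and -0.85), 2 of 9 flavonoid genes against 3 adjusted over the list alone (camera adjusted p = 0.0117, adjusted p = 0.506 with estimated correlation). Among repressors TFL1 and TEM2 rose (log2 1.54 and 1.81) and TOE1 and TOE2 fell (log2 -0.51 and -0.39), against 3 and 2 adjusted over the list alone (camera adjusted p = 0.976 toward lower, with a median above 0). LHP1, CLF and BRM rose (log2 0.38, 0.27 and 0.36), 3 of 15 chromatin factors against 4 adjusted over the list alone (0.0525). BOP1 fell (log2 -0.58), 1 of 20 against 0 adjusted over the list alone (0.49). PR1 fell (log2 -2.07), 1 of 9 against 2 adjusted over the list alone (0.291). The largest changes were in UGT76E2 and AT1G34440 (at least 20.3-fold higher each), QQS (log2 6.75), SEN1 (66.4 ± 88.2 against 1.04 ± 0.505 CPM) and AT1G22460 (1.43 ± 0.0690 against 0.0351 ± 0.0608). The largest falls were in AT5G09480 (at least 18.5-fold), AT3G58550 (at least 17.3-fold), AT2G38390 (0.0439 ± 0.0399 against 3.64 ± 0.680 CPM), AT5G44550 (0.0180 ± 0.0312 against 1.26 ± 0.319) and AT1G74460 (0.0259 ± 0.0449 against 1.15 ± 0.467). Calls numbered 2417, 1471 higher and 946 lower. The count was 1435 without WT 1, 1273 without WT 3 and 356 without quintuple 3. It was 285 in a fit of the 6 libraries alone, with 116 higher and more lower. SEN1, SEP4, LFY, LMI1, TOE1, TOE2, TEM2, GA20OX2, BOP1, LHP1, CLF, BRM, PR1, HSP101, HSP70, HSFA2, FLS1 and CHI lost their calls there. Without quintuple 3 the calls of TOE1 (adjusted p from 0.000615 to 0.103 over the fits without 1 library), GA20OX2 (0.00173 to 0.0521), GAI (0.0146 to 0.116), LHP1 (0.00159 to 0.221) and PR1 (0.0174 to 0.104) ended, with quintuple 3 the only library of the 6 to end them. Ended without quintuple 3 or another library were LFY (WT 1 or 2; 0.00873 to 0.258), LMI1 (WT 3 or quintuple 1; 0.0226 to 0.111), TEM2 (any WT; 0.0299 to 0.273) and TOE2 (WT 1 or 3 or any quintuple; 0.0299 to 0.182). BOP1 (WT 1 or 2 or quintuple 2; 0.0317 to 0.193), CLF (WT 3 or quintuple 2; 0.00379 to 0.266) and BRM (any WT or quintuple 2; 0.0293 to 0.274) ended likewise. The same held for HSP101 (WT 2; 0.00749 to 0.165), HSP70 (WT 2 or 3 or quintuple 1; 0.0151 to 0.223) and HSFA2 (WT 2 or quintuple 2; 0.0271 to 0.368). FLS1 and CHI ended without quintuple 3, any WT library or quintuple 1 (0.0256 to 0.262 and 0.0179 to 0.325).

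At 5 weeks all 13 floral promoters rose in quintuple adjusted over the list alone and 8 over all genes (camera adjusted p = 5.17e-25, and 5.16e-07 with estimated correlation). FD had 70.0 ± 3.3 CPM against 31.8 ± 5.45 in WT (log2 1.14, adjusted p = 6.26e-08), SPL9 90.4 ± 10.8 against 43.0 ± 3.81 and SPL4 4.37 ± 0.774 against 0.844 ± 0.403, and AGL42 rose by log2 1.46. FUL and UFO rose (log2 2.17 and 1.42), 2 of 9 floral identity genes, against 2 rises and 1 fall adjusted over the list alone (camera adjusted p = 0.0141, adjusted p = 0.176 with estimated correlation). SPL8 rose (log2 1.34), 1 of 5 genes of stamen, carpel and ovule development, against 2 rises and 1 fall adjusted over the list alone (camera adjusted p = 0.0457, adjusted p = 0.129 with estimated correlation). KNAT2 rose and CLV1 fell (log2 0.51 and -0.56), 1 each of 20 meristem and boundary genes, against 6 and 1 adjusted over the list alone (camera adjusted p = 0.00357, adjusted p = 0.394 with estimated correlation). ATX1 rose (log2 0.50), 1 of 15 chromatin factors against 3 adjusted over the list alone (camera adjusted p = 0.00132, adjusted p = 0.307 with estimated correlation). PR2 and PAD4 fell (log2 -3.76 and -1.43), 2 of 9 genes of salicylic acid defence against 3 adjusted over the list alone (camera adjusted p = 0.0174, adjusted p = 0.469 with estimated correlation). ZAT10 fell (log2 -3.23), 1 of 13 genes of wounding, touch and jasmonate against 4 adjusted over the list alone (camera adjusted p = 0.0029, adjusted p = 0.485 with estimated correlation). TFL1 rose and MAF5 fell (log2 1.38 and -1.66) among 14 repressors, also adjusted over the list alone (camera adjusted p = 0.714). GA2OX1 rose (log2 2.73), 1 of 19 against 3 adjusted over the list alone (0.0891). OLEO1 rose (log2 3.07), 1 of 4, also adjusted over the list alone (0.49). Of 11 vascular genes SUC2 rose and VND6 and XCP1 fell (log2 0.63, -1.57 and -1.23), against 1 and 5 adjusted over the list alone (0.094). AT1G34440 was at least 15.7-fold higher, QQS rose by log2 6.79, and CYP714A1 (1.93 ± 0.623 against 0.0230 ± 0.0398 CPM), AT5G37940 (2.87 ± 0.749 against 0.0516 ± 0.0893) and AT1G22460 (1.26 ± 0.109 against 0.0335 ± 0.0581) were the other largest rises. PP2-B14, AT2G18690, CML37, CYP706A2 and AT2G32140 had 0 reads in quintuple and were at least 87.9, 51.2, 26.5, 24.2 and 21.1-fold lower, with an SD above the mean in WT for all but AT2G32140. Calls numbered 1342, 500 higher and 842 lower. WT 3 lay apart from WT 1 and 2 on PC1 and PC2, and quintuple 3 also lay highest of its group on PC1. The count was 730 without WT 1, 552 without WT 2, 741 without quintuple 2 and 638 without quintuple 3, and 1912 without WT 3. In a fit of the 6 libraries alone it was 186. Calls lost there were those of AT2G32140, MAF5, TFL1, GA2OX1, CLV1, KNAT2, ATX1, VND6, XCP1, PR2 and PAD4. Ended without 1 library were the calls of PP2-B14 and MAF5 (WT 3; adjusted p from 0.00618 to 0.186 and 0.000598 to 0.0813) and AT2G18690 (WT 3 or quintuple 1 or 2; 0.0118 to 0.196). CML37 ended likewise (WT 1 or 3 or any quintuple; 0.045 to 0.257), as did CYP706A2 and AT2G32140 (WT 2 or 3 or any quintuple; 0.0316 to 0.339 and 0.0494 to 0.105). Lost too were TFL1 (WT 1; 0.00421 to 0.0683), CLV1 and XCP1 (WT 1 or 2 or quintuple 2 or 3; 0.00217 to 0.143 and 5.15e-05 to 0.26) and KNAT2 and SUC2 (any of the 6; 0.0563 to 0.167 and 0.0671 to 0.148). The rest were ATX1 (WT 1 or 2 or quintuple 1 or 3; 0.0122 to 0.181), OLEO1 (WT 1 or 2 or quintuple 1 or 2; 0.0179 to 0.119) and VND6 (WT 2 or quintuple 2 or 3; 0.000146 to 0.311), besides PAD4 (any WT or quintuple 1 or 2; 0.0343 to 0.16) and ZAT10 (WT 1 or 2 or any quintuple; 0.0412 to 0.124).

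At 6 weeks FUL had 23.3 ± 7.72 CPM in quintuple and 1.37 ± 0.296 in WT (log2 4.13, adjusted p = 5.27e-10), LFY 12.8 ± 4.13 against 3.65 ± 0.783 (log2 1.83, adjusted p = 2.93e-06) and FD 102 ± 10.4 against 33.9 ± 1.27 (log2 1.60, adjusted p = 9.8e-12). UFO and SEP4 rose (log2 1.55 and 1.19), as did FDP and SPL4 (log2 2.11 and 2.86) and SPL9 (100.4 ± 11.9 against 47.4 ± 9.48 CPM). In all 12 of 13 floral promoters rose, also adjusted over the list alone (camera adjusted p = 2.37e-38, and 5.14e-08 with estimated correlation), and 7 of 9 floral identity genes, also adjusted over the list alone (1.23e-10, and 0.000319). SPL8 and SHP1 rose (log2 1.53 and 2.16), 2 of 5 genes of stamen, carpel and ovule development against 3 adjusted over the list alone (camera adjusted p = 0.00314, and 0.0178 with estimated correlation). The MADS-box genes AGL6 and AGL72 were at least 40.9-fold and 28.9-fold higher, with 0 reads in WT. BOP2, KNAT2, CUC1 and KNAT6 rose (log2 0.99, 0.73, 0.96 and 0.79) and 1 gene fell among 20 of meristem and boundary, against 5 and 1 adjusted over the list alone (camera adjusted p = 0.00994, adjusted p = 0.469 with estimated correlation). PSBO1 fell (log2 -0.51), 1 of 10 photosynthesis genes against 3 adjusted over the list alone (camera adjusted p = 0.00185, adjusted p = 0.558 with estimated correlation). The flavonoid and anthocyanin list ranked higher with 0 of 9 genes called, also adjusted over the list alone (camera adjusted p = 0.0205, adjusted p = 0.558 with estimated correlation). TOE3 rose and TOE2 and TOE1 fell (log2 1.85, -0.79 and -0.41), against 1 and 3 adjusted over the list alone (camera adjusted p = 0.561). RGL2 and GA2OX2 rose and GA20OX2 fell (log2 0.95, 1.13 and -1.78), against 3 and 2 adjusted over the list alone (0.36), and COR47 fell (log2 -1.07), 1 of 7, also adjusted over the list alone (0.371). AT5G37940 (21.4 ± 11.9 against 0.0721 ± 0.0836 CPM), AT5G37950 (log2 6.58) and AT5G45630 (2.81 ± 0.188 against 0.0546 ± 0.0945) were the other largest rises. The largest falls were at least 26.8-fold for AT2G26750, 25.2-fold for ABCB16 and 15.2-fold for AT1G62450, and AT5G10580 had 0.0230 ± 0.0398 CPM against 4.41 ± 1.84 and NAS1, a nicotianamine synthase gene, 0.191 ± 0.209 against 12.5 ± 9.18. Calls numbered 1231, 551 higher and 680 lower. The count was 725 without WT 1 and 797 without quintuple 1. Dropping 1 library ended the calls of TOE1 without any WT library or quintuple 1 or 3 (adjusted p from 0.0299 to 0.224) and SHP1 without WT 1 or 3 or any quintuple library (0.0476 to 0.208). The call of GA20OX2 ended without quintuple 1 (0.0124 to 0.0649), RGL2 without WT 1 or 3 or quintuple 1 (0.0058 to 0.0735), GA2OX2 (0.00968 to 0.0847) without WT 3 or quintuple 2 or 3, KNAT6 (0.012 to 0.0761) without WT 2 or quintuple 2 or 3, PSBO1 without WT 1 or 2 or quintuple 2 or 3 (0.0421 to 0.225). The call of COR47 ended without WT 2 (0.00934 to 0.0557).

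**Figure D2:**
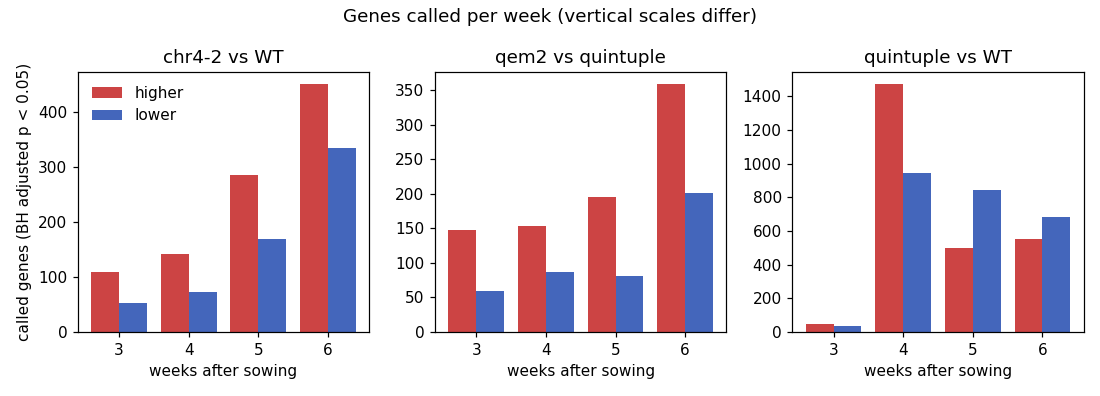
Genes called at BH adjusted p under 0.05 in each genotype comparison and week, with bars for higher and lower genes side by side. Vertical scales differ between the panels. The quintuple line differed from WT in 79 genes at 3 weeks and 2417 at 4 weeks.

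Many genes changed in the same direction in chr4-2 and in qem2. Called in both were 61, 77, 112 and 140 genes higher at 3, 4, 5 and 6 weeks, where independent lists would share 0.811, 1.11, 2.84 and 8.26, and 24, 32, 36 and 69 genes lower, where 0.157, 0.32, 0.695 and 3.43 would be shared. The smallest overlap by Fisher's exact test had p = 5.58e-49, one-sided over genes, which are not independent replicates. The comparisons share no library. AT1G48180 rose and AT4G25320 fell in both lines at every week. MRD1 rose in chr4-2 at every week and in qem2 at none (adjusted p = 0.898, 0.312, 0.248 and 0.633). Its mean difference, log2 -7.72, was untestable (standard error 387 at 3 weeks). Calls at all 4 weeks numbered 60 higher and 24 lower in chr4-2, 48 and 28 in qem2, and 30 and 17 in both. The shared genes fell from 148 to 84 at 5 weeks without qem2 1 and to 74 without qem2 2, and from 209 to 133 at 6 weeks without qem2 3. With both comparisons fitted on their own libraries alone the shared genes were 19, 67 and 79 at 4, 5 and 6 weeks, from 109, 148 and 209. With all 48 columns they were 38 at 5 weeks.

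**Figure D3:**
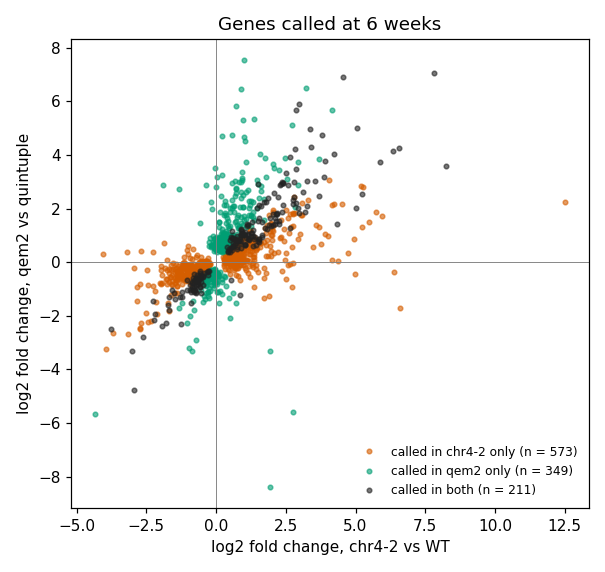
Log2 fold change of chr4-2 against WT and of qem2 against quintuple at 6 weeks for genes called in either. Colours mark genes called only in chr4-2, only in qem2 or in both.

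Whether a change in qem2 differed from that in chr4-2 was tested on the mean of the 4 weeks, and 93 genes differed. The largest signals were CHR4, ARP9 (an actin-related protein), AT2G47250, RECQ4B (a DNA helicase) and AT1G10730, with differences of log2 1.46, 1.17, 0.66, 0.90 and -0.79 (qem2 minus chr4-2, adjusted p = 8.54e-21, 3.26e-14, 1.27e-11, 2.9e-08 and 1.92e-06). Without qem2 6 weeks replicate 2 the count was 154. The change in chr4-2 differed between 6 and 3 weeks in 26 genes, led by AT5G01870, AT4G22490, AT1G10980, AUD1 and AT1G28710. Without WT 3 weeks replicate 1, 2 or 3 that count was 9, 16 and 14, and without chr4-2 3 weeks replicate 1 or 3 it was 14 and 16. It was 15 and 9 without WT 6 weeks replicate 1 or 3, and 14 and 11 without chr4-2 6 weeks replicate 1 or 3. The change in qem2 differed in 21 genes, led by AT1G34315, UBC11, MAF4, AT4G25320 and LFY. It was 144 without qem2 6 weeks replicate 2 and 11 without qem2 6 weeks replicate 3. The change in quintuple differed in 204 genes, led by AT2G38380, AT1G49450, TCP1, AT4G22485 and SPL4. It was 114 without WT 3 weeks replicate 1, 90 without quintuple 3 weeks replicate 1, 68 without WT 6 weeks replicate 1 and 71 without quintuple 6 weeks replicate 1. With DESeq2 the 4 counts were 150, 51, 47 and 309. With all 48 columns those over time were 10 for chr4-2 and 8 for qem2. With an absolute log2 of at least 1 that between backgrounds was 31. The named genes kept their calls without each library.

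The authors' tables of differential genes were compared with the calls by gene. Of the authors' genes, 134 of 182, 192 of 245, 341 of 692 and 712 of 966 were called in the same direction for chr4-2 in week order. For qem2 these were 185 of 315, 220 of 287, 258 of 472 and 479 of 651, and for quintuple 34 of 46, 465 of 486, 580 of 735 and 531 of 568.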

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

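Of the tests in this part, the 3 of the repeated column and that of the position of qem2 in the time course were chosen only after the result was seen.

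A signal outside the compared columns is the first pattern. The authors' 5 week qem2 table holds 14 genes whose mean is over 1.5 times that of the deposited columns, among them ZAT12, ERF13 and CBF1, against at most 1 in the other tables, which argues against use of the column as deposited in the authors' comparison. The column labelled qem2 5 weeks replicate 3 may hold quintuple counts under a qem2 label: over 86 genes its median position was 0.0205 between quintuple (0) and qem2 (1). Its counts are 92.41% of the mapped reads listed for quintuple 5 weeks replicate 3 (91.81 to 93.61% in the other listed libraries), which argues against qem2 counts under the quintuple label. No biological explanation was tested.

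The change differed between the backgrounds in 93 genes, among them CHR4 (log2 difference 1.46), ARP9 (1.17), AT2G47250 (0.66), RECQ4B (0.90) and AT1G10730 (-0.79). Without qem2 6 weeks replicate 2 the count was 154. Of the 84 genes called at all 4 weeks in 1 direction in chr4-2, 13 differed from qem2, among them CHR4, HEI10, FD and HDA18. Depth is argued against for CHR4 and AT4G34400, which stayed called with every library thinned to 2.91 M reads. It stays open for the rest: of the 13, 12 kept direction, but the median absolute difference (1.19 times that at full depth) grows with noise too. The ranges of depth by genotype overlapped (median 12.71 M in chr4-2 and 13.7 M in WT), which excludes nothing. Differences between lines in linked stretches of the genome stay open. Of the 13, 0 lay within 10 genes of another, as in random sets (median and 95th percentile 0), so the test could not tell. MRD1, outside the 13 as untestable, lies 2 genes from HEI10, so the 0 rests on its absence. The different alleles and backgrounds of the lines stay open as untested.

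LFY, AP1, AGL72 and CUC2 were called lower in qem2 than in quintuple at 6 weeks, AP1 with groups that overlapped, and DESeq2 called neither AP1 nor AGL72. Low depth of qem2 1 is argued against except for AP1: without it the median log2 of the 4 was -2.45, and AP1 alone lost its call. LFY differed between backgrounds at 6 weeks (log2 -2.24, adjusted p = 0.00054), which argues against a change with loss of CHR4 function in both. For CUC2 this stays open (adjusted p = 0.0758). In chr4-2 LFY had log2 0.72 and CUC2 0.05 (median 0.38). AP1 and AGL72 had at most 3 reads in chr4-2 and WT. Whether qem2 apices were earlier in the time course stays open: of genes rising in WT, 25 were higher and 19 lower in qem2 (exact binomial p = 0.451), and of genes falling in WT 61 were higher and 6 lower.

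The change in chr4-2 differed between 6 and 3 weeks in 26 genes, among them AT5G01870 (log2 difference -1.79), AT4G22490 (-1.67), AT1G10980 (-1.40), AUD1 (-0.87) and AT1G28710 (-1.31), a count that fell to 9 without WT 3 weeks replicate 1 or WT 6 weeks replicate 3. That in qem2 differed in 21, among them AT1G34315 (2.66), UBC11 (-1.63), MAF4 (-3.59), AT4G25320 (-1.23) and LFY (-2.35), with 144 without qem2 6 weeks replicate 2. That in quintuple differed in 204, among them AT2G38380 (5.83), AT1G49450 (4.48), TCP1 (2.49), AT4G22485 (-2.81) and SPL4 (4.01), with 68 without WT 6 weeks replicate 1.

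Libraries were regrouped in 60 splits, real one included, per difference test. Splits mix genotypes, so they cannot test for equal effects. At least the real count came in 2 for the backgrounds (93, highest other 551), a share under 0.05. It came in 8 for chr4-2 over time (26, 537), 5 for qem2 (21, 175) and 4 for quintuple (204, 379), so chance is not excluded. Splits with more calls point to a sample structure.

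For 3 against 3 libraries the 10 splits are too few for a share under 0.05. Real counts and the highest of the other splits were 160 and 0, 214 and 28, 453 and 91, and 784 and 0 for chr4-2 at 3 to 6 weeks. They were 206 and 0, 240 and 2125, and 560 and 97 for qem2 at 3, 4 and 6 weeks, 79 and 0, 2417 and 1354, 1342 and 449, and 1231 and 6 for quintuple, and 7426 and 1, 8989 and 172, 8128 and 1, and 6949 and 15 for time in WT, chr4-2, quintuple and qem2. At 4 weeks 3 of the 10 splits of qem2 and quintuple gave as many, the real one included. These splits ignore replicate numbers, which correlated there (0.363 to 0.542 over the 3 pairs). The real split parts all 3 pairs, and the 3 others that do so gave 0 genes each. The splits with 261 and 2125 genes part only 1 pair and set both libraries numbered 1 against both numbered 3. On the third principal component the libraries lay at -14.9 and -16.1 for number 1, -26.1 and -38.4 for 2, and -47.6 and -55.5 for 3, so that the structure goes with the replicate number, whose source is not stated. With the number as a block the count was 367. Of splits that part all 3 pairs the highest other gave 0 for chr4-2 at 4 and 5 weeks and qem2 at 3 weeks, and 52 for quintuple at 5 weeks, where all pairs correlated too. Elsewhere only the real split, 1 of 10, gave as many.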

How the results depend on the processing

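The setting with all 48 columns was chosen only after the data were seen. With RLE factors or no count filter each count of called genes stayed within 1.5 times the reported one, and RLE moved the median of all genes by at most 0.0245 (log2). No named gene reversed under any setting. Of named values, 539 of 544 kept their side of the threshold with RLE, 521 of 544 without the filter, 535 of 544 with DESeq2, 284 of 290 with the block within weeks, 251 of 254 with the additive block, 521 of 541 with 48 columns. It was 181 of 261 in fits of the compared libraries alone, whose lost calls are named with each comparison, and 3086 of 3538 without 1 library. Calls of named genes ended without the filter (F), with RLE (R), DESeq2 (D), the block (B) or 48 columns (C). In chr4-2 they were Prx37 (F), CUC1 (F, D, C), JRG21 and DIN11 (B) at 3 weeks, GA2 (F, C) and CRU3 (C) at 4, CESA7 (F, R, C) at 5 and TOE2 and GA3 (F, R, C) at 6. In qem2 they were AT2G20870 (F), MAF4 (F, C) and MAF5 (C) at 3 weeks, AP1 (F, D, B), AGL72 (D) and NPR1 (F) at 6, and AT3G24360, AT4G25320, AT2G30670, ZYP1b, AT2G43670, MAF5, CRU3 and FLC (C) at 5. In quintuple they were GRP9 (F, D) and EARLI1 (D) at 3 weeks, BRM (F, R) and TOE2, HSFA2, FLS1 and CHI (F) at 4, CML37, CYP706A2 and KNAT2 (F) at 5 and SHP1 (F) at 6. Over time they were LFY in qem2 (F, R, D, B), CHI in chr4-2 (F), CDKB2;2 in WT (B) and F3H (F), AP1 (D) and SESA1 (D, B) in quintuple, and of the differences over time AT1G10980, AT1G34315, UBC11 and AT4G25320 (C). Calls gained were SOC1 in chr4-2 at 6 weeks (D, B) and FLC in qem2 and quintuple at 4 weeks (B). For the counts that follow the cause was not tested, except that a fold minimum calls fewer genes by construction and fits of the compared libraries alone use fewer libraries. With an absolute log2 of at least 1 the counts were 99, 126, 229 and 386 for chr4-2, and 102, 127, 168 and 284 for qem2. They were 632, 662 and 655 for quintuple at 4 to 6 weeks, 2102, 2632, 2553 and 2301 for time in WT, chr4-2, quintuple and qem2, and 31 for the difference between backgrounds. In fits of the compared libraries alone they were 60 and 169 for chr4-2 at 4 and 5 weeks, and 1072, 26, 157 and 115 for qem2. They were 184, 285 and 186 for quintuple at 3 to 5 weeks, and 19, 67 and 79 for genes shared by chr4-2 and qem2 at 4 to 6 weeks. The block within weeks raised all counts (367 for qem2 at 4 weeks, 140 for quintuple at 3). With 48 columns the counts were 43 for qem2 at 5 weeks, 10 and 8 for the differences over time of chr4-2 and qem2 and 38 for genes shared at 5 weeks. DESeq2 gave 150 for the difference between backgrounds and 51, 47 and 309 for those over time of chr4-2, qem2 and quintuple. With an estimated correlation 18 of 63 list tests stayed called. Without 1 library the lowest and highest counts were 102 and 142, 137 and 181, 255 and 500, and 451 and 662 for chr4-2 in week order. They were 105 and 141, 148 and 394, 107 and 195, and 236 and 1158 for qem2, and 30 and 80, 356 and 3016, 552 and 1912, and 725 and 1025 for quintuple. They were 5891 and 6487, 7403 and 8721, 6551 and 7280, and 5564 and 6064 for time in WT, chr4-2, quintuple and qem2. They were 63 and 154 for the difference between backgrounds, 9 and 30, 11 and 144, and 68 and 241 for those over time of chr4-2, qem2 and quintuple, and 58 and 76, 84 and 108, 74 and 139, and 133 and 211 for shared genes.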

Other observations

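Of the tests in this part, that of the position of chr4-2 in the time course and that of the authors' WT library were chosen only after the result was seen.

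Whether genes of aliphatic glucosinolate synthesis, defence compounds made from methionine, were lower as a group in chr4-2 at 6 weeks was tested after CYP79F1 and BCAT4 were seen. Without these 2, 3 of 13 tested genes fell and 11 fell adjusted over the list alone, with a median log2 of -1.66 (camera p = 1.47e-09, adjusted p = 2.36e-08, and adjusted p = 0.426 with estimated correlation of 0.798). In qem2 at 6 weeks 0 of the 13 fell and 6 fell adjusted over the list alone (camera adjusted p = 3.83e-07, adjusted p = 0.426 with estimated correlation). A fall of the group in chr4-2 is a hypothesis that the preset test met and the estimated correlation did not.

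ZYP1b and MSH5, genes of meiotic recombination and synapsis, were lower in chr4-2 and in qem2 at each week, and HEI10 was higher in chr4-2 but not in qem2 (log2 -0.02 to 0.20). The hypothesis that such genes are lower as a group was not met: without the genes seen first, 1 of 19 rose and 0 fell in chr4-2 at 6 weeks, with camera p = 0.0201 toward higher (adjusted p = 0.0403, and 0.46 with estimated correlation). In qem2 the list was called at no week (lowest adjusted p = 0.679).

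The chr4-2 apices may have been further along the time course than WT at 6 weeks. Of 496 genes that rose over time in both quintuple and qem2, which share no library with this comparison, 62 were called higher in chr4-2 and 4 lower, and of 1163 that fell over time 40 were lower and 18 higher. An effect of CHR4 on the same genes apart from time would give these counts too.

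The authors' 5 week comparisons with WT may have left out WT 5 weeks replicate 3. The median ratio of log2 fold changes to the authors' was 0.839 for chr4-2 and 0.816 for quintuple with all WT libraries, and 0.999 and 0.994 without that library.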
